A study of Mus musculus with 15 samples.

How the data were processed

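Splicing was measured by RNA sequencing in 15 libraries of skeletal muscle from a mouse model of myotonic dystrophy type 1, a disease in which RNA with an expanded CUG repeat sequesters the muscleblind-like (MBNL) splicing factors. Per the labels, mice carried the TREDT960I transgene, whose transcript holds the repeat, and the MDAFrtTA transgene, whose product switches it on when doxycycline (dox) is given. At each of 6, 12 and 20 weeks of age there were 2 induced libraries (both transgenes, dox from postnatal day 1), 2 no-dox libraries (both transgenes, no dox) and 1 dox control (TREDT960I alone, with dox). The no-dox and dox-control libraries are together called controls, which gives 6 induced and 9 control libraries. The labels name gastrocnemius for 10 libraries and quadriceps for 5. A single library, week 6 no dox replicate 2, came from a male. RNA was poly-A selected and sequenced as paired-end reads of 100 bases, per the labels' protocols.

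The deposited table gives a fraction for each splicing event and library, the percent spliced in (PSI) on a scale of 0 to 1 printed to 2 decimals, per the file headers. The submitters' processing notes name TopHat and the mouse build mm10, and the deposited table's own name calls its fractions MISO output. The versions, the transcript annotation and any minimum number of reads are not given in the sources used here. No read counts accompany the fractions, so the depth behind each value is unknown. No interval or floor that needs depth is given, and an event with few reads weighs as much as one with many. For a skipped exon the fraction is taken as inclusion of the exon and for a retained intron as retention. For alternative first exons, last exons, splice sites and mutually exclusive exons it is reported only as PSI of the form the event lists as its own, without saying which end that is. Coordinates are those of the event names, on mm10 and counted from 1.

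Each library was matched to its column by the library identifier in its title. The column names number the pair of week 6 induced libraries the other way round from the titles, and the titles were followed. Of 39123 events, 31267 had a value in all 15 libraries and were tested. They lie in 8446 genes. The symbol column of the table named another gene than the gene ID in the event name for 5219 of the 8061 events that give both, so events named by gene ID were given the symbol of that ID in a RefSeq table of GRCm38.p6, and events named by coordinates kept the file's symbol where it lay at that position. The table holds 0 columns of other samples. Pearson's r of PSI between libraries lay between 0.943 and 0.968, and the closest pair had the same PSI in 18.9% of events, so no library appears to be deposited a second time. The labels describe libraries of individual muscles, but no animal numbers are given, so p-values measure the spread between these libraries.

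Differences in PSI were tested with limma 3.58.1 in R 4.3.3, with a variance trend and robust moderation, and p-values are two-sided with Benjamini-Hochberg adjustment over the events tested. The fit held a mean for each week in induced and control libraries plus a term for muscle, and the induced difference is the mean over the 3 weeks. Comparisons that separate no-dox from dox-control libraries used condition, week and muscle. An event was called at an adjusted p under 0.05 and a difference of at least 0.1 in PSI. Whether the induced difference varied between weeks was tested by a moderated F test of the interaction without a minimum difference. The tests, the alternatives, 12 gene lists and the rule for naming genes were fixed before the data were examined. For each list the text gives the calls over all events tested, the calls adjusted over the list alone, and Fisher's exact test, one-sided, of its share of genes with a call.

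The rule named up to 10 called events in each direction for induced against all controls, up to 4 called events per list, up to 5 called events in each direction for other comparisons, and, whatever the result, the event with the smallest p in each of Clcn1, Atp2a1, Bin1, Ldb3, Mbnl1, Mbnl2, Nfix, Cacna1s, Ryr1, Tnnt3, Dmd, Insr, Dtna, Pdlim3 and Camk2b. Because few events were called over all events, events called over a list alone and separated events were also named, and these were chosen after their values were seen. An event is called separated here if every one of the 6 induced libraries lay above, or every one below, all 9 controls with a difference in means of at least 0.1. That definition, an exact permutation test over the 5005 ways to choose 6 of 15 libraries, a weight per arm and random gene lists for the separated events were added after seeing the data.

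The fit was tested on simulated data drawn for the same 31267 events for induced against all controls. Noise was normal, with 1 spread per event for both arms and no effect of week or muscle. Differences were added only to events whose control mean was not close to 0 or 1. Of 50 events given a difference of 0.1, 5 were called. Of 50 each at 0.2, 0.3 and 0.4, 24, 31 and 47 were called, with 5 calls among 31067 unchanged events. In the real data the spread could be larger in induced libraries, as in the Ldb3 exon (SD 0.128, against 0.009 in controls). These counts therefore need not hold for the real data. Alternatives were the logit of PSI held within 0.01 to 0.99, no minimum difference or one of 0.2, events with at least 12 values, events with a mean PSI of 0.05 to 0.95, no muscle term, each muscle alone, each week alone, the replicate number as a block, females alone, no variance trend or robust moderation, and each library left out in turn. Figures and summaries were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The 7856 events with a value in some but not all libraries were left out of the tests.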

Results

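The table held PSI of 39123 splicing events in 15 muscle libraries, 5 at each of 6, 12 and 20 weeks. Each library had a value for between 34416 and 36959 events. The 31267 events measured in every library comprised 9294 skipped exons, 7178 alternative last exons, 4618 alternative first exons, 3578 alternative 3' splice sites, 2287 alternative 5' splice sites, 2192 retained introns, 1120 tandem UTRs and 1000 mutually exclusive exons. Read depth per event is unknown.

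The main question was which events differ between muscle with the induced CUG repeat and muscle without it. A 100-nt exon of Tspan9, a tetraspanin of the cell membrane (chromosome 6, 128078027 to 128078126), was included at 0.173 ± 0.164 (SD, n = 6) in induced and 0.049 ± 0.030 (SD, n = 9) in control libraries. This rise of 0.124 (SE 0.012, limma adjusted p = 0.017) came mostly from week 6, where the induced libraries were at 0.33 and 0.43, while those of weeks 12 and 20 lay between 0.05 and 0.09. PSI of an alternative first exon of Adgrl3, a latrophilin adhesion receptor, fell from 0.567 ± 0.058 (SD, n = 9) to 0.342 ± 0.118 (SD, n = 6), a difference of -0.225 (SE 0.024, limma adjusted p = 0.020), with 5 of 6 induced libraries below all controls. These were the only 2 events called by limma over all 31267, and 1958 (6.26%) had an unadjusted p under 0.05. The count was 40 without week 6 induced replicate 1, 17 without week 12 induced replicate 2, 5 without week 6 induced replicate 2, 1 without the week 6 dox control and 0 without either week 6 no-dox library, any of the 3 week 12 controls or either week 20 no-dox library. Adgrl3 also lost its call without the week 6 dox control, week 6 induced replicate 2 or either week 20 induced library. Tspan9 also lost its call on the logit scale, with an adjusted p of 0.0774. The count was also 0 without a muscle term. It was 0 with mean PSI of 0.05 to 0.95, where both events had an adjusted p of 0.0567. In gastrocnemius and quadriceps alone it was 0 too, with adjusted p-values of 0.9935 and 0.9471 for Tspan9 and of 0.9690 and 0.9341 for Adgrl3. Both calls ended in the exact permutation test, which adjusted no event under 0.05, with 26 events at its smallest p of 2.00e-04. Even that smallest p adjusted to 0.240, so no event could keep a call there and the loss decides nothing about these 2. Unadjusted, the exact permutation p was 0.0206 for Tspan9 and 4.00e-04 for Adgrl3.

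Exons of the muscleblind-like factors themselves were more included in induced muscle. MBNL proteins regulate splicing of their own transcripts. A 54-nt exon of Mbnl1 (chromosome 3, 60614683 to 60614736) rose from 0.057 ± 0.013 (SD, n = 9) to 0.215 ± 0.095 (SD, n = 6), and the 54-nt exon of Mbnl2 (chromosome 14, 120395712 to 120395765) from 0.078 ± 0.011 to 0.190 ± 0.067. A 1049-nt exon of Mbnl1 (chromosome 3, 60528756 to 60529804) rose from 0.596 ± 0.046 to 0.808 ± 0.080, and PSI of an alternative first exon of Mbnl1 rose from 0.509 ± 0.034 to 0.667 ± 0.064. In the exons of Mbnl1 and Mbnl2 all 6 induced libraries lay above all 9 controls, and for the first exon 5 of 6 did. Their limma p adjusted over the MBNL list alone lay at 0.0044 for Mbnl2 and the 1049-nt exon, 0.0055 for the 54-nt exon of Mbnl1 and 0.0058 for the first exon. Over all events the adjusted p was 0.107 for Mbnl2, 0.069 for the 1049-nt exon, 0.146 for the 54-nt exon of Mbnl1 and 0.171 for the first exon. Without week 6 induced replicate 2 the difference of the Mbnl2 exon was 0.091, under the minimum of 0.1.

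Other genes of the MBNL list changed as well. Inclusion of a 79-nt exon of Clcn1, the muscle chloride channel (chromosome 6, 42293444 to 42293522), rose from 0.154 ± 0.067 (SD, n = 9) to 0.442 ± 0.244 (SD, n = 6), with 4 of 6 induced libraries above all controls. A 42-nt exon of Atp2a1, the calcium pump of the sarcoplasmic reticulum (chromosome 7, 126446545 to 126446586), was at 1.00 in all 9 controls and fell to 0.738 ± 0.204 in the 6 induced libraries, which ranged from 0.41 to 0.93. A 186-nt exon of Ldb3, a Z-disc protein (chromosome 14, 34555343 to 34555528), rose from 0.029 ± 0.009 to 0.245 ± 0.128, and a 303-nt exon of the giant sarcomere protein Ttn (chromosome 2, 76705670 to 76705972) from 0.460 ± 0.082 to 0.657 ± 0.148. A 123-nt exon of the transcription factor Nfix (chromosome 8, 84723728 to 84723850) rose from 0.268 ± 0.026 to 0.462 ± 0.109. In Clasp1, which encodes a protein of microtubule ends, a 24-nt exon (chromosome 1, 118541675 to 118541698) rose from 0.193 ± 0.047 to 0.475 ± 0.173 and a 48-nt exon (chromosome 1, 118512175 to 118512222) fell from 0.681 ± 0.086 to 0.452 ± 0.103. The limma p adjusted over the MBNL list alone was 0.0058 for Clcn1, 0.0146 for Atp2a1, 0.0055 for Ldb3 and Nfix, 0.0363 for Ttn, and 0.0087 and 0.0300 for the Clasp1 exons. Over all events these adjusted p-values lay between 0.143 and 0.348. The call of Ttn over the list was lost in 18 of 28 alternatives, including every single library left out except week 6 or week 12 induced replicate 1 or week 20 induced replicate 2. That of the 48-nt Clasp1 exon was lost in 13 of 28, including every single library left out except week 6 no dox replicate 2, week 12 no dox replicate 2, the week 12 dox control or week 6 or week 12 induced replicate 1. Atp2a1 lost its call without week 12 induced replicate 2 (adjusted p = 0.0606) or week 20 induced replicate 1 (0.0774), and Clcn1 and Ttn lost theirs in the exact permutation test, both with an adjusted p of 0.0751.

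**Figure D1:**
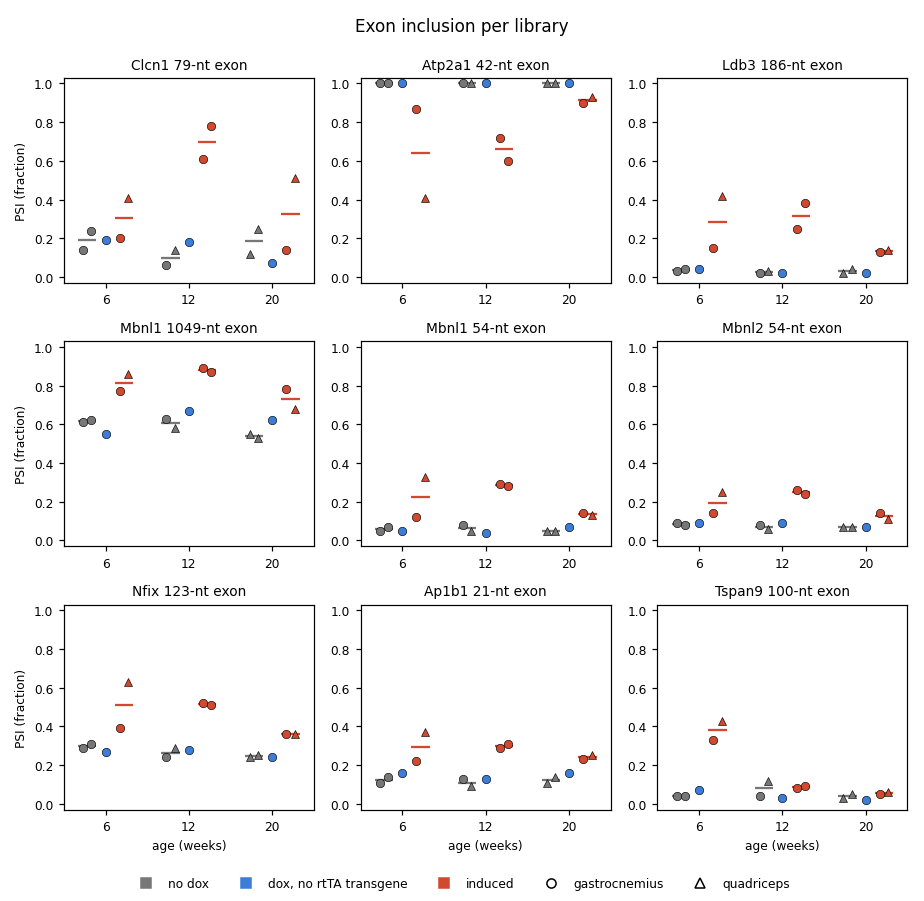
PSI (fraction, vertical axis) of 9 exons in each library by age in weeks (horizontal axis), with gray for no dox, blue for dox controls, red for induced, circles for gastrocnemius, triangles for quadriceps and short lines for means of 2 libraries. The 42-nt exon of Atp2a1 is at 1.00 in all 9 controls and between 0.41 and 0.93 in the induced libraries, and the 100-nt exon of Tspan9 is at 0.33 and 0.43 in induced libraries of week 6.

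The list of genes whose splicing is known to depend on MBNL proteins or to change in myotonic dystrophy held 45 tested genes with 358 events. Adjusted over the list alone, 11 events in 8 genes were called, 9 higher and 2 lower in induced muscle, and 0 were called over all events tested. Separated events, a definition added after seeing the data, occurred in 5 of the 45 genes (11.11%) and in 17 of 8401 other genes (0.20%), with adjusted p = 1.01e-06 in Fisher's exact test. In 10000 random gene lists matched on events per gene, the p was 1.00e-04, the smallest that they can give, or 0.0012 after adjustment. The count of 11 was 24 without week 6 induced replicate 1 and 0 with gastrocnemius or quadriceps libraries alone. With gastrocnemius alone the lowest adjusted p over the list was 0.0516.

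Further events of the fixed genes were not called. Cacna1s, the voltage sensor of muscle, had a 57-nt exon (chromosome 1, 136104570 to 136104626) at 0.997 ± 0.005 (SD, n = 9) in controls and 0.95 ± 0.044 (SD, n = 6) in induced libraries. A 93-nt exon of Bin1, a protein of membrane tubules (chromosome 18, 32414945 to 32415037), was at 0.009 ± 0.003 and 0.045 ± 0.028, and every induced library lay above every control. The limma p adjusted over the MBNL list was 0.0058 for Cacna1s and 0.0070 for Bin1, and both missed only the minimum difference of 0.1. A 129-nt exon of Camk2b (chromosome 11, 5977812 to 5977940), a calcium-dependent kinase, was at 0.859 ± 0.039 and 0.750 ± 0.125, with a limma p adjusted over the MBNL list of 0.0915. PSI of an alternative last exon of Dtna, a dystrophin partner, was 0.570 ± 0.067 and 0.482 ± 0.063 with an adjusted p of 0.0869 over the list. Adjusted p-values over the list were 0.5401 for a 41-nt exon of Tnnt3 (chromosome 7, 142513665 to 142513705), 0.6655 for Insr, 0.7038 for Dmd and 0.8547 for Ryr1, and the Pdlim3 event was at 0 in every library.

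Kinase and vesicle genes gave further calls over their own lists. Of 307 events in 47 genes of insulin signalling, kinases and phosphatases, 8 events in 5 genes were called adjusted over the list alone, 5 higher and 3 lower. They included a 231-nt exon of Map4k4 (chromosome 1, 40003757 to 40003987), which rose from 0.247 ± 0.077 (SD, n = 9) to 0.458 ± 0.147 (SD, n = 6), a 132-nt exon of Wnk1, a regulator of ion transport (chromosome 6, 119953771 to 119953902), which rose from 0.288 ± 0.044 to 0.433 ± 0.063, and a 63-nt exon of the casein kinase Csnk1d (chromosome 11, 120964948 to 120965010), which fell from 0.489 ± 0.054 to 0.352 ± 0.047. A 96-nt exon of Rapgef1, an exchange factor for small GTPases (chromosome 2, 29720643 to 29720738) fell from 0.457 ± 0.046 to 0.297 ± 0.060 and a 69-nt exon of Ktn1, which encodes a kinesin receptor and neither a kinase nor a phosphatase (chromosome 14, 47704420 to 47704488) from 0.882 ± 0.050 to 0.738 ± 0.046. The limma p of the 8 lay between 0.0270 and 0.0452 adjusted over that list and between 0.184 and 0.348 over all events, and 4 events of the list were called on the logit scale. Their calls were lost in 156 of 224 values under alternatives, and each was lost in 16 to 22 of 28. These 8 are not all separate changes. A pair of alternative last exon events of Csnk1d had nearly the same PSI in every library, with means of 0.490 and 0.493 in induced libraries. The 132-nt Wnk1 exon overlaps a 462-nt exon of Wnk1 (119953771 to 119954232) that is also among the 8. All 8 were lost without any one of either week 6 no-dox library, week 6 induced replicate 2, the 3 week 12 controls, week 20 no dox replicate 1 and either week 20 induced library. Without any other library 1 to 4 were kept, except without week 6 induced replicate 1, where all 8 were. Of 327 events in 50 genes of endocytosis and vesicle traffic, 2 were called, both higher. They were a 21-nt exon of the clathrin adaptor Ap1b1 (chromosome 11, 5033242 to 5033262), at 0.130 ± 0.023 in controls and 0.278 ± 0.057 in induced libraries, and mutually exclusive exons of Dnm2, the dynamin of membrane fission, at 0.090 ± 0.023 and 0.213 ± 0.061, each with an adjusted p of 0.0192 over the list and of 0.146 and 0.171 over all events. Both calls were lost without week 12 no dox replicate 2, week 12 induced replicate 2, either week 20 no-dox library or week 20 induced replicate 1, and that of Dnm2 also without week 6 induced replicate 2. In gastrocnemius alone the adjusted p was 0.2017 for Ap1b1 and 0.3416 for Dnm2, in quadriceps alone 0.8776 and 0.9255, and all 8 calls of the kinase list were lost in either muscle alone.

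Among genes of regenerating or developing muscle, 3 of 32 events were called adjusted over the list alone, all lower in induced libraries. A 30-nt exon of the adhesion molecule Ncam1 (chromosome 9, 49550540 to 49550569) fell from 0.490 ± 0.109 (SD, n = 9) to 0.287 ± 0.073 (SD, n = 6). PSI of an alternative last exon of Myh8, the perinatal myosin heavy chain, fell from 0.626 ± 0.167 to 0.218 ± 0.213 and that of an alternative first exon from 0.129 ± 0.094 to 0.015 ± 0.015, and all 3 had an adjusted p of 0.0196 over the list and between 0.420 and 0.435 over all events. All 3 calls were lost without week 12 induced replicate 1 or week 20 induced replicate 1, those of Ncam1 and the Myh8 last exon without week 6 induced replicate 2, and that of the Myh8 first exon without the week 20 dox control. In gastrocnemius alone all 3 were lost, with an adjusted p of 0.0554 for Ncam1, 0.0909 for the Myh8 last exon and 0.0697 for its first exon, and in quadriceps alone Ncam1 and the Myh8 first exon were lost. The list of RNA-binding proteins gave 4 calls over the list alone, all in Mbnl1 and Mbnl2. Excitation-contraction coupling gave 2, in Clcn1 and Atp2a1, the sarcomere list 1, in Ldb3, and the transcription list 1, in Nfix. Events in 54 genes of the sarcolemma and its cytoskeleton, 31 of energy metabolism, 25 markers of other cell types and 26 broadly expressed control genes gave 0 calls by limma, with 55, 11, 8 and 2 events at an unadjusted p under 0.05 and 0 calls on the logit scale. No list held an event called by limma over all events, so Fisher's exact test on those calls could not pass for any list. On logit calls, a choice made after seeing the data, the MBNL, RNA-binding and regeneration lists passed it, with adjusted p = 5.82e-07, 0.0113 and 0.0265. The regeneration list passed through Myh8 alone among its 7 tested genes, by the first exon, which lay between 0 and 0.04 in induced libraries. The RNA-binding list passed through Mbnl1 and Mbnl2 alone. The lists share genes, and the RNA-binding list has 4 in common with the MBNL list, Mbnl1 and Mbnl2 among them. On separated events the MBNL and kinase lists passed, with adjusted p = 0.0391 for the kinases, which became 0.0894 against matched random lists.

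The time course asked at which ages the splicing differences were present. At week 6 the 79-nt exon of Clcn1 was at 0.20 and 0.41 in the induced libraries against a mean of 0.190 in the 3 controls, with a fitted difference of 0.034 (SE 0.087). At week 12 it was at 0.61 and 0.78 in the induced libraries against a mean of 0.127 in the 3 controls, and at week 20 at 0.14 and 0.51 against 0.147. The limma p that its induced difference varied between weeks was 0.0021 unadjusted and 0.9923 adjusted over all events. The exon of Ldb3 was at 0.15 and 0.42 in induced libraries of week 6, 0.25 and 0.38 at week 12, and 0.13 and 0.14 at week 20, with controls between 0.02 and 0.04. Tspan9 was the 1 event called at week 6, with a difference of 0.303 (SE 0.022, limma adjusted p = 0.0025), and on the logit scale 0 were called there. At week 20 the 1 called event was an alternative last exon of Map3k2, a kinase of stress signalling, whose PSI rose to 0.17 and 0.16 from 0.05 or less in controls (difference 0.126, SE 0.008, limma adjusted p = 7.40e-04). At week 12 limma called 0 events, with 1888 at an unadjusted p under 0.05 and 1 call on the logit scale.

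The Map3k2 event was also the 1 event whose induced difference varied between weeks (limma adjusted p = 0.0148), and for Tspan9 this adjusted p was 0.1302. The count of events varying between weeks was 0 without any of the 3 week 6 controls, week 12 no dox replicate 2, week 12 induced replicate 1, week 20 no dox replicate 1 or the week 20 dox control. It rose to 31 without week 12 induced replicate 2. The Map3k2 event was not among those with a mean PSI of 0.05 to 0.95, and both of its calls ended with that limit. Counts rested on single libraries, with 39 calls at week 6 without week 6 induced replicate 1, 129 at week 12 without week 12 induced replicate 2 and 20 at week 20 without week 20 induced replicate 1. Fitted to the libraries of their own week alone, weeks 6 and 20 gave 0 calls. Across the 31267 events, which are not independent replicates, Pearson's r of the differences was 0.048 between weeks 6 and 12, -0.002 between weeks 6 and 20 and 0.052 between weeks 12 and 20. Over the 358 events of the MBNL list, a choice made after seeing the data, r was 0.518, 0.084 and 0.347. No library is shared between weeks. These differences are plain means of induced minus control libraries of each week, without a muscle term. Quadriceps was more frequent in induced than in control libraries at week 6 and less frequent at weeks 12 and 20. A difference between muscles thus enters week 6 in the opposite direction, and its effect on r was not tested.

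**Figure D2:**
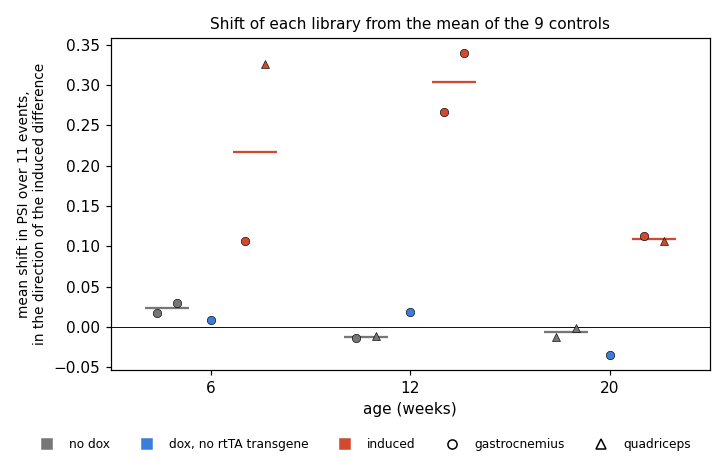
Mean shift in PSI (vertical axis) over the 11 events of the MBNL list called over the list alone, taken in the direction of the induced difference, for each library by age in weeks (horizontal axis), with a control set against the other controls, colors and symbols for group and muscle, and short lines for means of 2 libraries. Induced libraries are at 0.107 and 0.326 at week 6, 0.267 and 0.340 at week 12 and 0.113 and 0.106 at week 20, and controls lie between -0.035 and 0.029.

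The 11 events chosen above shifted to different extents in the induced libraries. The mean shift was 0.107 in week 6 replicate 1 and 0.326 in replicate 2, 0.267 and 0.340 at week 12, and 0.113 and 0.106 at week 20. All 11 events lay beyond the range of the controls in week 6 replicate 2 and in both week 12 libraries, 10 in week 20 replicate 1, and 8 in week 6 replicate 1 and week 20 replicate 2. The 42-nt exon of Atp2a1 was at 0.87 and 0.41 at week 6, 0.72 and 0.60 at week 12 and 0.90 and 0.93 at week 20. Week 6 replicate 2 and week 20 replicate 2 were quadriceps and the other induced libraries gastrocnemius. With 2 libraries against 2, an exact test between ages cannot go below p = 0.333.

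Separate comparisons with each kind of control asked whether dox or genotype contributes to the differences. In Mbnl1 the 1049-nt exon was at 0.587 ± 0.040 (SD, n = 6) without dox and 0.613 ± 0.060 (SD, n = 3) in dox controls, against 0.808 ± 0.080 (SD, n = 6) in induced libraries. The exon of Ldb3 was at 0.030 ± 0.009 and 0.027 ± 0.012 in the 2 kinds of control, and that of Atp2a1 at 1.00 in every library of both. The fitted differences between dox control and no dox, whose week and muscle terms come from all 15 libraries, parted from these means, at 0.032 (SE 0.056) for Ldb3 and -0.060 (SE 0.087) for Atp2a1. Limma called 0 events between induced and no-dox libraries, with 1881 at an unadjusted p under 0.05 and a smallest adjusted p of 0.2214, and 0 between induced libraries and dox controls, with 1368 and 0.4259. Between dox controls and no-dox libraries it called 0, with 1118 at an unadjusted p under 0.05. These 2 kinds of control differ in both dox and the MDAFrtTA transgene, whose effects cannot be told apart here. The limma fits of these comparisons called 0 events on the logit scale too. The exact permutation test over the 9 controls gave 691 events at an unadjusted p under 0.05 and 0 after adjustment. Its p cannot go below 0.0119, far too high for adjustment over 31267 events, so its 0 decides nothing.

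Muscle and age were compared because both vary over the libraries. PSI of an alternative last exon of Mov10, an RNA helicase, was higher in quadriceps at 0.15 to 0.26 than in gastrocnemius at 0.03 to 0.08, a difference of 0.138 (SE 0.010, limma adjusted p = 0.0030). It was the 1 event called between muscles, with 2356 at an unadjusted p under 0.05. All 5 quadriceps libraries have later library numbers in the labels than all 10 gastrocnemius libraries, so muscle and a difference between series of libraries cannot be told apart. In controls, 0 events were called by limma between weeks 20 and 6, with 1663 at an unadjusted p under 0.05, a smallest adjusted p of 0.3032 and 0 calls on the logit scale. The 41-nt exon of Tnnt3 was at 0.51 and 0.24 in the 2 no-dox libraries of week 20, both quadriceps, and at 0.96 or above in the 13 others. An interaction of muscle with induction gave 0 events, with 1547 at an unadjusted p under 0.05 and a smallest adjusted p of 0.064.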

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

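All tests of explanations in this part were chosen after the result was seen, and the tests of a swap and of an admixture, and the rule that a single library excludes nothing, were revised after earlier versions of these tests had been computed.

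Single libraries stood apart from the rest of their arm in 4 of 42 groups examined, where chance gives about 1 in 20. The Tspan9 exon was at 0.12 in week 12 no dox replicate 2, against 0.07 or less in the other controls. The Bin1 exon was at 0 in week 6 no dox replicate 1 and at 0.01 in the other 8 controls, the smallest step the table prints. In week 6 induced replicate 2 the 41-nt exon of Tnnt3 was at 0.96, against 0.99 or above in the other induced libraries, and the Camk2b exon at 0.51, against 0.75 or above. The induced difference of the Map3k2 event varied between weeks with a limma adjusted p of 0.0148, and the induced libraries of week 20 were at 0.17 and 0.16 where those of weeks 6 and 12 were at 0.02.

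Events with missing values were left out of all comparisons, and 7 of these 7856 events had a value in all 6 induced libraries and in 0 of 9 controls, while 0 had the reverse pattern. They lie in Slc2a6 (2 events), Aldh3a1, Rhbdl2, Sytl1, AC125279.2 and Tnnt3. Of the 1000 splits of the libraries within weeks, 1, the real one, gave as many, and the highest of the others was 2. Chance is thus unlikely for this count, although the pattern was chosen after it was seen. With up to 2 controls allowed, 29 events were listed, among them events in Cx3cl1, Rsad2, Zap70, Serpina3g and Dsp, against 2 with no induced and at least 7 control libraries. These genes were named after their values were seen, and a missing value is not a measure of expression.

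The larger shift of week 6 induced replicate 2 (0.326) than of replicate 1 (0.107) held in 11 of 11 events of the MBNL list. The mean difference was 0.219 (SE over events 0.033). These events were called with both libraries in the fit, and an SE over events, here and below, does not measure the spread between animals. A swap of replicate 1 with a control needs a control with an induced pattern, and the highest mean shift of a control was 0.029. Of 24 events called over the list without replicate 1, this library lay beyond the controls in 12, against at most 6 for any control. The 11 and the 24 events were called with the controls labelled as such, which favored events in which no control stood apart. The low values of the controls come partly from that choice and do not exclude a swap. Muscle could account for the pattern and cannot be told apart from the animal, because weeks 6 and 20 have 1 induced library of each muscle, although at week 20 quadriceps minus gastrocnemius was -0.0064 (SE over events 0.0433). Admixture of uninduced muscle RNA also stays open, since equal ratios of the shifts in all events gave a chi-square p of 0.011 with the spread of the controls and 0.93 with a spread scaled to each PSI. The 2 events called over all events go against equal ratios, since replicate 1 shifted 0.74 times as far as replicate 2 for Tspan9 and 0.89 times for Adgrl3, against a fitted 0.26 or 0.29 in the 11 events, but they are outside the list and were called with replicate 1 in the fit, so they exclude nothing.

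The mean shift was 0.194 smaller at week 20 than at week 12 (SE over events 0.0245), and both week 12 libraries exceeded both week 20 libraries in 10 of 11 events. In the induced direction controls moved by -0.0127 (SE over events 0.0085) from week 12 to week 20. The shifts of both weeks were taken against the same mean of all controls. A movement of the controls alone therefore cannot produce the difference of 0.194. A drift with age shared by both arms would enter that difference in full. The controls moved by only -0.0127 over these 11 events, which argues against a shared drift as its main source. Muscle and the later library numbers of week 20 cannot be told apart from age, because a single library bears on each. The gastrocnemius library of week 20 lay below both week 12 libraries in 11 of 11 events, and the week 6 library with a later number had a shift of 0.326. An effect of age in induced animals alone and variation between animals in repeat expression stay open and were not tested.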

How the results depend on the processing

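The exact permutation tests, separated events, random lists for them, the weight per arm, logit calls for the lists and the correlation over the MBNL list were chosen after seeing the data. Depth per event is unknown, so its effect could not be examined.

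For induced against all controls, the count of 2 became 9 on the logit scale, where Tspan9 lost its call and Adgrl3 kept it, 5 without a minimum difference, 4 without variance trend and robust moderation, 1 at a minimum difference of 0.2, 26 as separated events, and 0 with mean PSI of 0.05 to 0.95, without a muscle term, in gastrocnemius or quadriceps alone, in females alone and in the exact permutation test. Leaving out single libraries gave 0 to 40 calls. On the logit scale week 6 gave 0, week 12 gave 1, weeks differing gave 7 and muscle 2, and muscle gave 2 without a minimum difference. With mean PSI of 0.05 to 0.95 week 20 and weeks differing gave 0, and with the libraries of their week alone weeks 6 and 20 gave 0. Single libraries left out gave 1 to 39 calls at week 6 (39 without week 6 induced replicate 1, 2 without week 6 induced replicate 2, the week 6 dox control or week 12 no dox replicate 2), 0 to 129 at week 12 (129 and 2 without its induced replicates 2 and 1, 9 without either week 6 induced library, 1 without week 12 no dox replicate 1) and 1 to 20 at week 20 (20 and 4 without its induced replicates 1 and 2, 2 without week 20 no dox replicate 2). They gave 0 to 31 for weeks differing (31 without week 12 induced replicate 2, 8 and 2 without week 20 induced replicates 1 and 2, 5 and 2 without week 6 induced replicates 1 and 2, 2 without week 12 no dox replicate 1, the week 12 dox control or week 20 no dox replicate 2, and 0 without any week 6 control, week 12 no dox replicate 2, week 12 induced replicate 1, week 20 no dox replicate 1 or the week 20 dox control). Without week 12 no dox replicate 2 the counts were 2 between muscles, from a range of 1 to 2, and 1 each for induced against dox control, dox control against no dox and age in controls, from ranges of 0 to 1. Where a group kept 1 library, it was assumed to vary like the others.

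Of the MBNL list, 11 events became 24 without week 6 induced replicate 1 (range 8 to 24), 6 at a minimum difference of 0.2 and 0 in gastrocnemius or quadriceps alone. All 11 kept their direction in 28 settings, but these are not 28 separate checks. The logit scale, the minimum differences, the limits on values and mean PSI, and the moderation leave the PSI difference itself unchanged, so its sign could not change there. Females alone is the same fit as leaving out week 6 no dox replicate 2. The number of lists passing Fisher's exact test, which had to be 0 because no list held a limma call over all events, was 3 with logit calls, 2 with separated events, 1 with matched random lists for these, and 3, 3 and 4 with weeks 6, 12 and 20 left out. Lists share genes, so passes of different lists are not independent. The correlations of weeks became 0.518, 0.084 and 0.347 over the MBNL list. The replicate numbers do not pair the libraries (correlations of 0.010, -0.012 and 0.015 at weeks 6, 12 and 20), and with a replicate block 0 events were called against all controls or no dox and 0 over the MBNL list, and the calls of the kinase and vesicle lists and of the Myh8 first exon were lost (adjusted p = 0.0665 for the last). Of 1535 values of the 55 named events under alternatives, 291 lost a call, 12 gained one, and 1 changed sign, the uncalled induced difference of the Mov10 event, at 0.012 and at -0.003 with gastrocnemius alone. The settings that leave the difference unchanged are among these values too. Fewer libraries entered the fits by muscle, by week and with a library left out, and otherwise the cause was not tested.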

Other observations

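The hypothesis and the separated events in this part were chosen after the values were seen.

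Further separated events had not been named above. A 149-nt exon of Synj2, a phosphoinositide phosphatase (chromosome 17, 6036357 to 6036505), was at 0.186 ± 0.041 (SD, n = 9) in controls and 0.370 ± 0.065 (SD, n = 6) in induced libraries. Mutually exclusive exons of Chka, a choline kinase, were at 0.116 ± 0.040 and 0.308 ± 0.092, and a 35-nt exon of Pdp1, a phosphatase of pyruvate dehydrogenase (chromosome 4, 11965614 to 11965648), at 0.036 ± 0.009 and 0.137 ± 0.085. A 6-nt exon of Clip1, a linker at microtubule ends (chromosome 5, 123581592 to 123581597), was at 0.063 ± 0.028 and 0.267 ± 0.152. Lower in all induced libraries were a 79-nt exon of the cap-binding protein Eif4e2 (0.770 ± 0.037 and 0.628 ± 0.090), a 39-nt exon of Prc1, a spindle protein (0.350 ± 0.074 and 0.163 ± 0.054), and a retained intron of Ankzf1 (0.379 ± 0.122 and 0.157 ± 0.045). PSI of alternative first exons of the transcription factors Runx1 and Trp63 and of the chromatin remodeler Chd3 was higher in all induced libraries. None of these was called by limma over all events, and 39 events were separated before the minimum difference, where chance gives at most 12.5 on average, a number that a single split can exceed.

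Of 100 splits drawn from the 1000 splits of the libraries within weeks, 1, the real one, gave 26 separated events, and the highest of the others gave 10. Chance is thus unlikely for this count, but it is not excluded, because the definition was added after seeing the data and the share cannot go below 1 of 100. Other splits gave up to 10 such events, so single separated events can still be due to chance. For the 2 limma calls of induced against all controls, 2 of 100 splits, the real one included, gave as many, with 3 in the highest other. This share is under 0.05, but a chance split exceeded the real count, so chance is unlikely for the count and not excluded. With 0 real calls every split gives as many, so the splits decide nothing for induced against no dox (100 of 100, highest other 1), induced against dox control (27 of 27, highest other 3) and dox control against no dox (27 of 27, highest other 1). For the 1 call between muscles, 5 of 100 splits gave as many, with 2 in the highest other, and chance is not excluded. For age in controls the 10 splits are too few for a share under 0.05, with 0 real calls, 1 in the highest other and 10 of 10 as large.

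A hypothesis was that separated exons keep the reading frame more often than others. Of 16 separated skipped exons, 10 (62.5%) had a length divisible by 3, against 4124 of 8721 other exons (47.3%), and Fisher's exact test, one-sided, gave p = 0.1669, so the data did not settle it. The median length was 71 nt for separated and 107 nt for other exons.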
